A study of Oryza sativa with 2 samples.

How the data were processed

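Root RNA of rice seedlings, wild type or carrying XVE:PP2CABA-dHA, was labelled with biotin and hybridised to Affymetrix Rice GeneChip arrays, 1 array per genotype, per the labels. The arrays were processed with MAS5, per the submitters' processing notes. The MAS5 version and the genome build behind the probe annotation are not given in the sources used here. The authors deposited 1 table with each array's signal, detection call and annotation, and the series' value table with the same signals to 1 decimal.

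MAS5 summarises the probe pairs of a probe set, usually 11 here, into 1 intensity on a linear scale, and the deposited intensity values had been scaled by the authors so that the mean after trimming 2% at each end was 500.1 on both arrays. The header of these columns calls them raw, but they are scaled signals. Signals under 1 had been set to 1 in the deposited table (2238 in wild type and 1538 in transgenic roots). The columns called normalized were found to be log2 of the same signals with no further scaling, as deposited by the authors. MAS5 also gives each probe set a detection p-value within its array, and the authors deposited it with calls of Present under 0.05 and Absent over 0.065, Marginal between. The authors' deposited table gives a log2 ratio and a linear fold of transgenic over wild type, which equal the signal ratio without any filter, and by which 9453 probe sets were at least 2-fold higher and 7173 at least 2-fold lower in the authors' deposited table. These were not used further, since most such folds rest on signals near background. The value table differed from the signals by more than rounding at 71 and 55 probe sets, by at most 2.90 and 7.28, and was used as an alternative.

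From these signals a log2 ratio of transgenic over wild type was computed per probe set after both signals were raised to a floor of 9.997, the higher of the arrays' median signals over Absent probe sets (8.22 in wild type, 9.997 in transgenic roots). A probe set was counted when it differed by at least 2-fold and was Present on the brighter array. Where the dim array was not Present, the fold against the higher of the floor and the dim signal is written as a lower bound. Where a dim signal near the floor was called Present, the fold is a rough size. The 123 control probe sets were left out. With 1 array per group no test across arrays is possible, and the number of arrays limits the precision. As a sign of the noise of a probe set, 1006 genes with several probe sets Present on both arrays had a median range of log2 ratio of 0.25, with a 90th percentile of 0.79. Of 79 such genes whose first probe set passed 2-fold, the last went the same way in 73 and passed 2-fold in 44. Dim probe sets differed more often: in 4 equal classes of signal among probe sets Present on both arrays, dimmest first, 15.9%, 15.5%, 11.0% and 7.35% passed 2-fold.

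Hybridisation controls added in fixed amounts, 18 probe sets Present on both arrays, had a median log2 ratio of -0.05 and a range of -0.26 to 0.39. The ratio of 3′ to 5′ signal, a sign of RNA quality, was 8.33 in wild type and 9.40 in transgenic roots for actin, 7.63 and 6.26 for GAPDH, 2.81 and 2.95 for cyclophilin and 0.752 and 0.758 for ubiquitin. A further actin control gave 7.07 and 7.20, and further GAPDH and ef1a controls had an end near background and give no usable ratio. For actin and GAPDH, though not for ubiquitin, the 3′ end was thus several times as bright as the 5′ end on both arrays. Whether this bias affects probe sets far from the 3′ end was not tested. Median signals of Present probe sets were 500.1 and 508, and log2 signals of probe sets Present on both arrays had a Pearson r of 0.931, taken across probe sets, which are not independent replicates.

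Gene identities came from the transcript assignments in the deposited table. A probe set took the locus that most of its probes matched, with at least 9 probes required, a rule set once the tables were in hand, which gave 41093 probe sets an MSU locus and 29150 a RAP locus. Descriptions are those of the deposited annotation, of unknown release, and can be old. The platform's annotation table lists 1 gene for 22436 probe sets, several for 95 and none for 34850, and through it and the RefSeq gene table for assembly ASM3414082v1 a symbol was found for 110. No coordinates are given. Probe sets marked as shared between transcripts (10006) can read related genes as well.

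The following were fixed before the data were examined: the measure, the floor, the 2-fold threshold, the alternatives, 37 gene lists defined by locus or by words in the description, and the rule for naming genes. That rule takes every measured clade A PP2C, the 15 highest and 15 lowest log2 ratios among counted, described genes on unshared probe sets, and up to 2 of the highest and 2 of the lowest counted members of each list. Each list used 1 probe set per gene, the one with the highest mean log2 signal, among genes Present on at least 1 array. Lists with at least 5 measured genes got a median, a 95% interval from order statistics over genes, which is no replicate error, and a percentile among 10000 random lists of the same size matched on mean signal in 20 bins.

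Some lists caught genes by wording that do not belong. The jasmonate list took a pair of outward-rectifying potassium channels, and its median was 0.53 with and without them. Further such members were a folylpolyglutamate synthase among nitrogen genes, haloperoxidase-related proteins among peroxidases, a calcyclin-binding protein among cyclins, actin-binding proteins and chloroplast dehydrogenases among reference genes, basic 7S globulins among seed storage genes, and many GID1L2-type carboxylesterases among gibberellin genes. Several iron genes described as transposon proteins are yellow stripe-like transporters by synonym.

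The counting was tested on simulated data for the transgenic against wild-type comparison, with 57258 probe sets, noise of 0.2 (SD, log2) and 200 bright probe sets changed. All 200 were recovered at 4-fold and all 200 at 8-fold, with 10 and 5 unchanged probe sets counted; the noise was assumed, not measured. Alternatives changed the scaling (median-centring, quantile normalization), the floor, the detection filter, the fold threshold and the choice of probe sets. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.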

Results

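Transcript levels were measured in roots of rice seedlings on Affymetrix Rice GeneChip arrays, which carry 57381 probe sets. One sample came from the wild type and the other from the transgenic line XVE:PP2CABA-dHA, with 1 array for each. XVE is a chimeric transcription factor that estradiol activates and that is used to switch a transgene on. Seedlings of both genotypes were 2 days old when 1 µM β-estradiol was added, and roots were taken after 8 days, so the inducer was present in both samples. Of the 57258 probe sets left after the array controls, 29371 (51.3%) were called Present in wild-type roots and 28902 (50.5%) in transgenic roots, and 27101 on both arrays. Because each group had 1 array, no difference given here has a replicate check, no p-value was computed, and effects of the array, the RNA sample and the genotype cannot be told apart.

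The comparison asks which transcripts differ between wild-type and XVE:PP2CABA-dHA roots, both given the inducer. Without an uninduced transgenic sample, an effect of induction cannot be told apart from other differences between the lines. Expression of the transgene itself was not measured. In the transgenic roots, genes of jasmonate synthesis and response, WRKY transcription factors and pathogenesis-related proteins had higher signals as groups, and photosynthesis genes had lower signals almost without exception. The largest single differences were transcripts near background in wild type and bright in transgenic roots, among them a lipid-transfer protein, a fatty acid elongase and enzymes annotated as jasmonate O-methyltransferases. Most measured core components of abscisic acid (ABA) signalling lay within 2-fold of wild type. These were the 4 receptors measured, most SnRK2 kinases and most clade A protein phosphatases 2C (PP2C). Across all probe sets, 2402 (7.71% of the 31172 Present on at least 1 array) were at least 2-fold higher in transgenic roots and 2418 (7.76%) at least 2-fold lower, each Present on the brighter array. Those higher belonged to 2235 genes and those lower to 2176. The dim array was not Present for 875 of the higher and 576 of the lower probe sets, whose folds are lower bounds written as "at least". Differences of 16-fold or more were found for 231 higher and 56 lower probe sets. The median log2 ratio of transgenic to wild type over probe sets Present on both arrays was 0.04, with quartiles of -0.25 and 0.30.

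**Figure D1:**
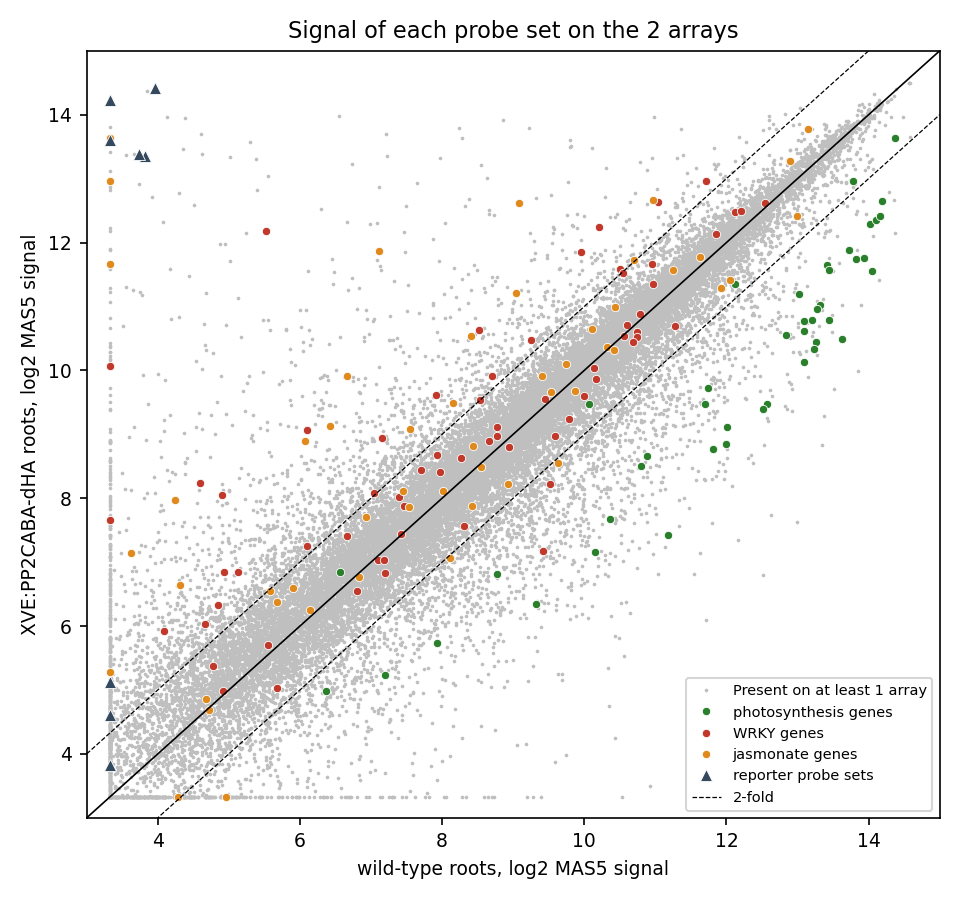
Log2 MAS5 signal of each probe set Present on at least 1 array, wild-type roots on the x axis and XVE:PP2CABA-dHA roots on the y axis, with signals under the floor of 9.997 drawn at it. The solid line marks equal signal and the dashed lines 2-fold; 39 of the 44 photosynthesis genes (green) lie at or under the lower dashed line, while WRKY (red) and jasmonate genes (orange) extend far above the upper one, and 5 reporter probe sets (triangles) reach signals over 10000 on the transgenic array alone.

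Clade A PP2Cs dephosphorylate SnRK2 kinases and are inhibited by ABA-bound receptors, and 7 of the 8 on the array were measured. OsPP2C30 was the only one at least 2-fold higher, Absent in wild type at a signal of 71.9 and Present in transgenic roots at 146 (at least 2.03-fold), and its log2 ratio of 1.02 became 0.90, under 2-fold, with quantile normalization. The log2 ratios were 0.66 for OsPP2C08, 0.40 for OsPP2C09, 0.19 for OsPP2C53, -0.03 for OsPP2C06, -0.16 for OsPP2C68 and -0.50 for OsPP2C50. The other probe set of OsPP2C06 gave 0.53. OsPP2C51 was Absent on both arrays. The list median was 0.19 (95% interval -0.50 to 1.02), at percentile 80.3 of 10000 random lists of equal size matched on mean signal, a comparison that describes these 2 arrays only. Outside clade A, 1 of 34 measured PP2C genes was higher and 1 was lower (median 0.09). The higher one, described as PP2C isoform epsilon (LOC_Os06g48300), had a signal of 39.2 (Absent) in wild type and 12131 in transgenic roots, at least 310-fold. A shared probe set of the same gene read 93.6 and 267, a log2 ratio of 1.51. The lower one was LOC_Os03g16760, at least 2.25-fold. The labels do not tie the name PP2CABA to a locus, so no probe set was taken as a readout of the transgene.

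ABA receptors of the PYL family showed no member past 2-fold among 4 measured, with log2 ratios of 0.05 for OsPYL6, -0.08 for OsPYL11, -0.32 for OsPYL1 and -0.95 for OsPYL2. Of 10 SnRK2 kinases, which relay ABA signals by phosphorylating bZIP factors, SAPK8 was 2.04-fold higher (signals of 4858 and 9913) and 9 stayed within 2-fold, for a list median of -0.08 (percentile 15.1). Among 6 ABA-related transcription factors, OsbZIP46 was 2.51-fold lower and 5 were within 2-fold (median 0.08, percentile 64.4). Genes of ABA synthesis and breakdown held no member past 2-fold among 7 (median 0.20, percentile 77.6). Late embryogenesis abundant proteins, dehydrins and other ABA-responsive genes, which accumulate in drying tissue, went both ways, with 4 of 25 higher and 2 lower. The abscisic stress ripening genes LOC_Os01g72910 and LOC_Os01g72900 were 4.36-fold and 3.49-fold higher, whereas the bright member LOC_Os11g06720 was 2.40-fold lower and dehydrin COR410 2.65-fold lower. Their list median was -0.24 (95% interval -0.40 to 0.24), at percentile 0.48. No stress NAC, DREB or HD-Zip factor passed 2-fold among 14 (median 0.15, percentile 77.7), although 1 was at least 2-fold lower with quantile normalization.

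**Figure D2:**
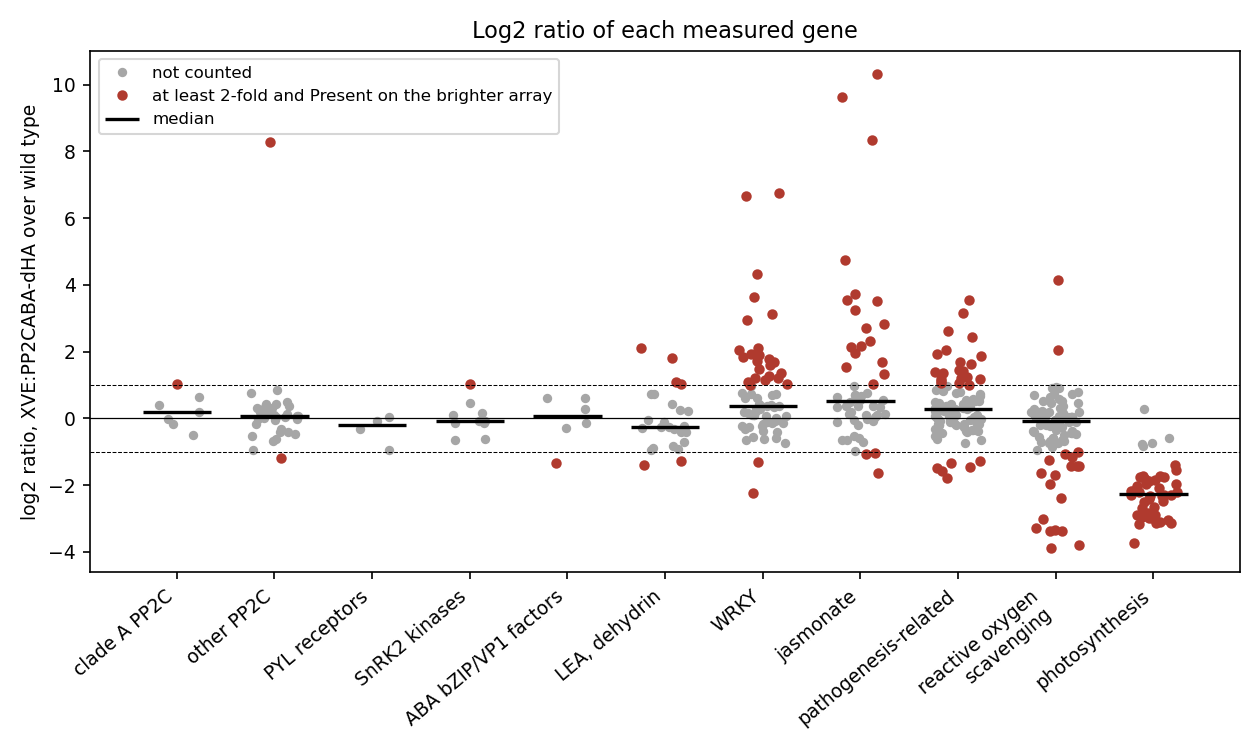
Log2 ratio of transgenic over wild-type signal for each measured gene of 11 lists, 1 point per gene and 1 array per genotype. Black bars are list medians, dashed lines mark 2-fold, and red points are at least 2-fold and Present on the brighter array. Photosynthesis genes sit around a median of -2.25, and ABA signalling lists lie mostly between the dashed lines.

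The brightest of the 15 genes with the highest ratios were a 3-ketoacyl-CoA synthase (LOC_Os01g34560), an enzyme that elongates very long chain fatty acids, and a nonspecific lipid-transfer protein (LOC_Os10g36100). The former read 14.5 in wild type and 21189 in transgenic roots (1464-fold, a rough size since 14.5 lies near the floor), and the latter 5.91 and 19821 (at least 1983-fold). Genes described as jasmonate O-methyltransferase, LOC_Os06g20770 and LOC_Os02g48770, were at least 1267-fold and at least 801-fold higher; the first lies under a probe set that also matches another locus. The receptor-like kinase ARK1AS (LOC_Os01g02370) was at least 916-fold higher, a carbonic anhydrase (LOC_Os08g32750) at least 895-fold, the serine carboxypeptidase-like SCPL51 at least 442-fold and cytochrome P450 76C2 at least 383-fold. A gene described as MYB96, named after an Arabidopsis regulator of cuticular wax synthesis, was at least 307-fold higher, and its other probe set gave a log2 ratio of 5.55. A gene named for the maize sex determination factor tasselseed-2 (LOC_Os07g46920) was at least 242-fold higher. The other genes of this set were a von Willebrand factor type A domain protein (at least 180-fold), the proline-rich protein APG (180-fold), a ribosomal RNA apurinic site lyase (at least 168-fold) and cytochrome P450 51 (at least 138-fold). The other probe sets of the lipid-transfer protein and of LOC_Os07g46920, both shared, gave log2 ratios of 10.48 and 7.42. All of these genes were called Absent in wild type except the 3-ketoacyl-CoA synthase and APG.

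Among the 15 lowest genes, a phosphoglucomutase family member (LOC_Os06g28194) went from a signal of 1945 in wild type to 11.3, Absent, in transgenic roots (at least 172-fold), although its other probe set was Absent on both arrays. A polygalacturonase non-catalytic beta subunit (LOC_Os10g26940) was at least 147-fold lower, a plant-specific domain protein (LOC_Os01g62060) at least 72.6-fold and the meiotic pairing homolog LOC_Os06g27860 at least 67.0-fold. A pair of cysteine-rich receptor-like kinases named CRK10, LOC_Os07g43570 and LOC_Os07g43560, were at least 58.5-fold and at least 42.4-fold lower. Bounds of 54.4-fold, 32.6-fold, 32.5-fold and 32.4-fold belonged to a pumilio-type RNA-binding protein, cytochrome P450 76C4, terpene synthase 7 and a 3Fe-4S ferredoxin (LOC_Os06g28050). The rest included the leaf isozyme of ferredoxin-NADP reductase (at least 30.3-fold), a Rubisco small subunit (LOC_Os12g19470, 28.1-fold), lactoylglutathione lyase (23.2-fold), a thylakoid phosphoprotein (23.0-fold) and cytosolic fructose-1,6-bisphosphatase (22.5-fold). The other probe set of that Rubisco gene read 14414 and 3423, a smaller log2 ratio of -2.07. For LOC_Os06g28050, the other probe sets gave -1.44 and -1.24. Those of the ferredoxin-NADP reductase and the fructose-1,6-bisphosphatase gave -3.58 and -2.44, also smaller than the named ones (log2 ratios of -4.92 and -4.49).

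Jasmonate genes were higher as a group, with 18 of 52 measured at least 2-fold higher and 3 lower. Their median log2 ratio was 0.53 (95% interval 0.15 to 0.97), above all 10000 matched lists, and 0.37 over the members Present on both arrays. Besides the methyltransferases, the higher members included a chloroplast lipoxygenase (LOC_Os12g37320, at least 324-fold) and ZIM-motif genes, the family of JAZ repressors that jasmonate itself induces, such as LOC_Os09g26780 (27.1-fold) and LOC_Os03g08320 (11.6-fold); these 3 genes were picked after their values were seen. The lower members were LOC_Os07g05840 (at least 3.12-fold, and within 2-fold with a doubled floor), the 12-oxophytodienoate reductase LOC_Os01g27230 (2.11-fold) and a further methyltransferase, LOC_Os01g50610 (2.06-fold, picked after its value was seen).

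WRKY factors, many of which regulate defence genes, had 24 of 67 members higher and 2 lower, with a median of 0.38 (95% interval 0.15 to 0.75), again above all matched lists. LOC_Os01g60520 was at least 107-fold higher and WRKY transcription factor 38 (LOC_Os11g02470) 101-fold, while OsWRKY23 was 4.74-fold lower and OsWRKY18 2.45-fold. OsWRKY76 and OsWRKY62, both bright, were 4.13-fold and 3.72-fold higher (picked after their values were seen). Pathogenesis-related proteins, a class of chitinases, beta-glucanases and antimicrobial proteins, had 21 of 96 higher and 6 lower. The PRB1-3 type gene LOC_Os07g03288 was 11.7-fold higher, under a probe set that matches several loci. The beta-glucanase LOC_Os01g71380 was 8.89-fold higher on a shared probe set. Pathogenesis-related protein 10 (LOC_Os12g36840) was 3.42-fold lower and chitinase 1 (LOC_Os10g28120) 2.99-fold lower. Other genes of these names went the other way: LOC_Os12g36830, also described as pathogenesis-related protein 10, had a log2 ratio of 0.68. A further chitinase 1 (LOC_Os10g28080) was 2.61-fold higher. The median was 0.28 (95% interval 0.09 to 0.42), above all matched lists. Phenylpropanoid and lignin genes had 16 of 51 higher and 7 lower (median 0.24, percentile 99.7). A caffeic acid O-methyltransferase (LOC_Os04g01470) was at least 32.0-fold higher and another (LOC_Os04g09604) at least 10.2-fold lower, and dirigent-like proteins, which steer lignan coupling, went both ways, 7 of 18 higher and 4 lower, with LOC_Os08g26110 at least 18.3-fold higher on a probe set that matches several loci and LOC_Os11g07770 at least 21.7-fold lower. Class III peroxidases, cell wall enzymes, had 12 of 99 higher and 14 lower (median -0.07, percentile 1.14). Peroxidase 1 (LOC_Os01g22249) was at least 54.4-fold higher and peroxidase 43 (LOC_Os11g10460) was 33.1-fold higher. Another peroxidase 43 (LOC_Os12g08920) had a log2 ratio of 0.27. Peroxidase 68 (LOC_Os02g14440) was at least 52.4-fold lower on a shared probe set, and another peroxidase 68 (LOC_Os02g14430) was 2.51-fold lower. In the diterpenoid phytoalexin list 4 genes were measured, all described as ent-kaurene synthase A or B. These descriptions name no phytoalexin, so the list is no measure of phytoalexin synthesis. A gene described as ent-kaurene synthase A (LOC_Os02g17780) was 2.87-fold higher, and just under 2-fold (log2 ratio 0.99) with a doubled floor.

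**Figure D3:**
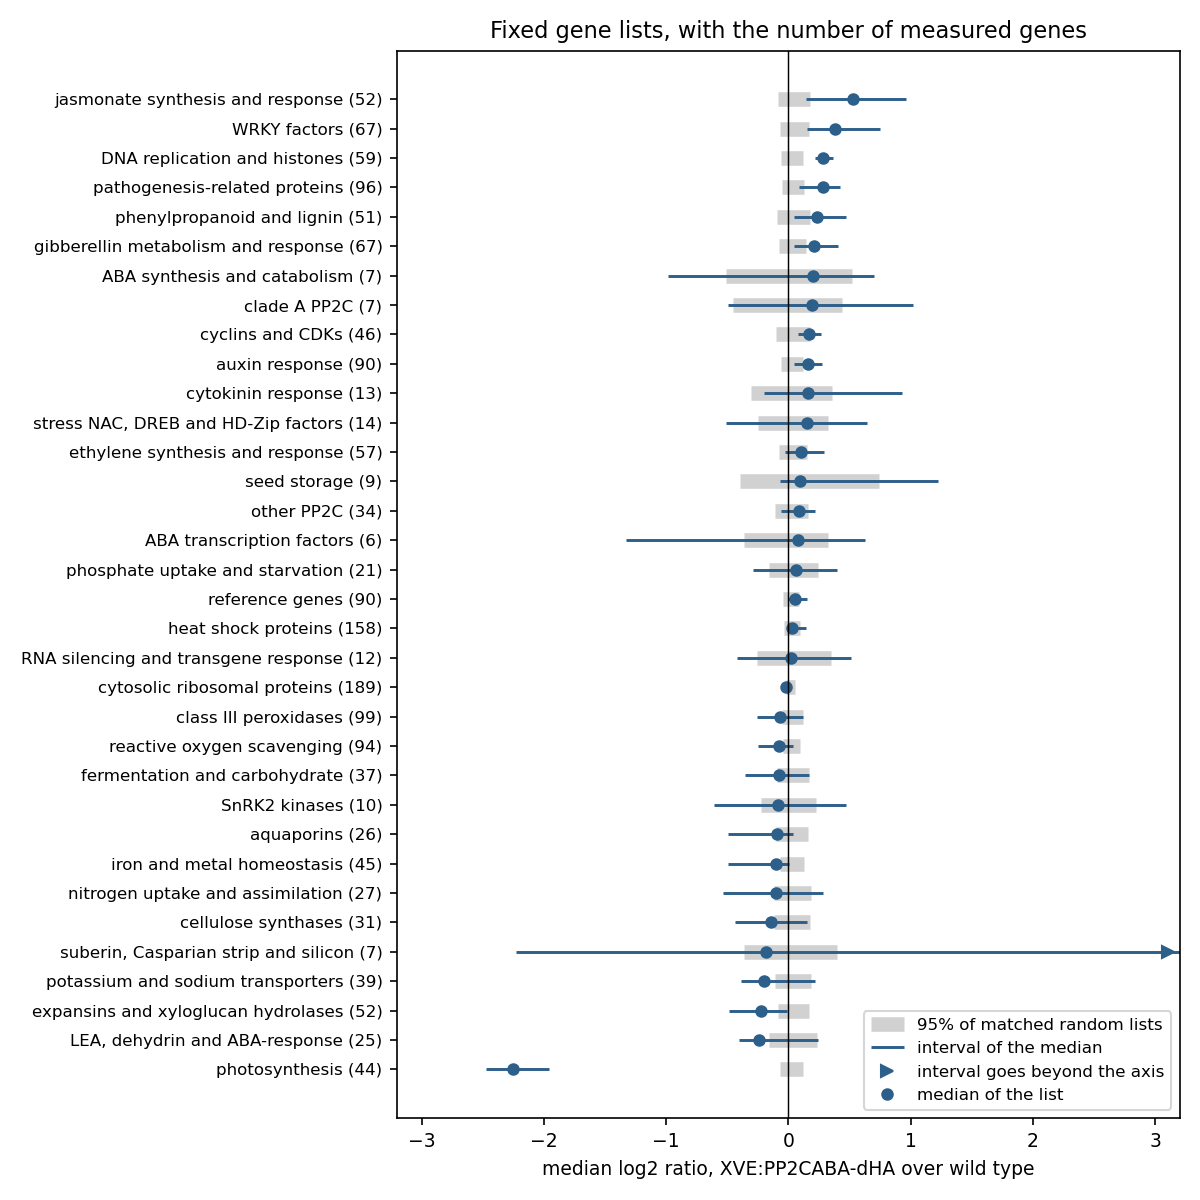
Median log2 ratio of each fixed gene list with at least 5 measured genes (number in brackets), transgenic over wild-type roots, 1 array each. Points are medians, lines their 95% intervals over genes, and grey bars span the central 95% of 10000 random lists matched on size and mean signal. The interval of the suberin list, on 7 genes, runs past the axis to 10.52; the photosynthesis median of -2.25 lies farthest from its random lists.

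Photosynthesis genes, fixed as a marker of green shoot tissue, were lower in transgenic roots for 43 of 44 members, 39 of them at least 2-fold and none at least 2-fold higher. The median log2 ratio was -2.25 (95% interval -2.48 to -1.96), under all matched lists. A chlorophyll a-b binding protein (LOC_Os09g26810) was 13.4-fold lower and Rubisco activase (LOC_Os11g47970) 8.91-fold lower. Of the 44 members, 39 were Present on both arrays. The photosystem II polypeptide LOC_Os08g10020 was bright in both samples, at 18283 in wild-type and 5432 in transgenic roots. So was a probe set of the Rubisco small subunit LOC_Os12g19470, at 14414 and 3423. Both were picked after their values were seen and do not stand for the class. Of the 2418 lower probe sets, 233 had descriptions naming chloroplasts or photosynthesis, against 23 of the 2402 higher ones. Without such probe sets the counts were 2379 higher and 2185 lower.

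Reactive oxygen scavenging genes had 18 of 94 lower and 2 higher (median -0.08, percentile 0.25). Catalase-1, a peroxisomal enzyme, was 14.9-fold lower (signals of 4333 and 292) and a glutathione S-transferase (LOC_Os10g38710) 13.9-fold lower. Of the other lower members, 4 are described as chloroplast or thylakoid proteins, led by the ascorbate peroxidases OsAPx8 (log2 ratio -3.38) and LOC_Os04g51300 (-3.36), while the cytosolic OsAPx1 and OsAPx2 (-0.01 and -0.05) and the stromal OsAPx7 (-0.01) lay near 0 (picked after their values were seen). By these descriptions, which can be old and do not settle where a protein lies, the split is not clean. Members not described as chloroplast proteins were as low, LOC_Os08g41090 (-3.35), LOC_Os02g09940 (-3.28) and LOC_Os06g09610 (-3.01). Whether these are chloroplast proteins was not tested. The chloroplast superoxide dismutases LOC_Os08g44770 and LOC_Os06g05110 stayed within 2-fold (-0.59 and -0.66). The glutathione S-transferases LOC_Os01g27340 and LOC_Os10g38140 were at least 17.7-fold and 4.18-fold higher. Nitrogen genes had 4 of 27 higher and 2 lower (median -0.10, percentile 4.06). Both lower ones are described as chloroplast enzymes of ammonium assimilation, a glutamate synthase (13.3-fold) and a glutamine synthetase (3.74-fold). An ammonium transporter (LOC_Os11g01410) was at least 3.22-fold higher and a nitrate transporter (LOC_Os01g50820) 2.71-fold higher. In the phosphate list 3 of 21 were higher and 1 lower, and the lower one was the chloroplast phosphate transporter LOC_Os02g38020 (8.26-fold). The root-type transporter LOC_Os10g30790 was 2.72-fold higher and LOC_Os03g05610 at least 2.24-fold, the latter under 2-fold with quantile normalization (log2 ratio 0.90). The phosphate median of 0.06 (percentile 55.3) changed sign to -0.11 under that normalization. Heat shock proteins and their DnaJ partners had 1 of 158 higher and 10 lower, led by a heat shock protein binding protein (LOC_Os12g31460, 9.32-fold) and a DnaJ-like protein (LOC_Os01g42190, 8.21-fold). Their median of 0.03 (percentile 49.0) became -0.00414 after median-centring, and the single higher member, a heat shock cognate gene, was under 2-fold with quantile normalization (log2 ratio 0.85), where another member passed 2-fold in its place. Reference genes had a median of 0.06 (percentile 84.2) over 90 members, 1 higher and 4 lower, and the lowest were the chloroplast glyceraldehyde-3-phosphate dehydrogenases A (10.4-fold) and B (10.4-fold), photosynthetic enzymes. The higher one was an actin binding protein (LOC_Os04g38810, at least 3.56-fold).

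Among hormone genes, the gibberellin list had 14 of 67 higher and 7 lower (median 0.21, percentile 99.9). Many of its members, most of the higher ones among them, are GID1L2-type carboxylesterases caught by wording. The count and median are therefore not a measure of gibberellin genes alone. A gene described as the receptor GID1L2 (LOC_Os09g28280) was 33.4-fold higher, another GID1L2 (LOC_Os07g06850) at least 3.36-fold lower, and genes described as gibberellin 20 oxidase 2, an enzyme of gibberellin synthesis, were at least 9.06-fold higher (LOC_Os05g34854) and 3.61-fold lower (LOC_Os03g42130). Auxin response genes had 4 of 90 higher and 3 lower, with 60 above 0 (median 0.16, percentile 99.6). Auxin efflux carrier component 5 was 4.16-fold and OsIAA14 3.49-fold higher, whereas OsIAA2 was 4.65-fold and OsSAUR39 4.0-fold lower. Of 13 cytokinin genes (median 0.16, percentile 77.6), a gene described as cytokinin dehydrogenase 1 (LOC_Os01g10110), an enzyme that degrades the hormone, was at least 28.7-fold higher. The other 12 were within 2-fold. Among these were LOC_Os01g09260 and LOC_Os01g71310, of the same description, each with a log2 ratio of 0.93. Ethylene genes had 8 of 57 higher and 5 lower (median 0.11, percentile 88.5). An ethylene-responsive protein (LOC_Os10g30150) was 29.5-fold higher and the ACC oxidase LOC_Os02g53180, which makes ethylene, 4.77-fold lower.

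DNA replication genes and histones were higher by small amounts in 53 of 59 members, and 2 of them passed 2-fold, both histone H2B genes, LOC_Os09g39730 (5.19-fold) and LOC_Os01g05900 (2.11-fold). The median of 0.28 (95% interval 0.22 to 0.36) lay above all matched lists. Cyclins and cyclin-dependent kinases had 3 of 46 higher and none lower (median 0.17, percentile 96.7), with cyclin delta-2 19.8-fold higher and cyclin-A2 2.47-fold, the latter a dim probe set that was within 2-fold with a doubled floor. Cytosolic ribosomal proteins had 1 of 189 lower and none higher (median -0.02, percentile 1.88), and the lower one, LOC_Os12g37610, was 2.42-fold lower. Expansins and xyloglucan hydrolases, which loosen the growing cell wall, were lower on balance (median -0.22, 95% interval -0.48 to -0.01, percentile 0.03), with 4 of 52 higher and 5 lower at 2-fold. The xyloglucan hydrolase LOC_Os04g51520 was at least 6.24-fold lower and alpha-expansin 15 at least 3.70-fold lower, while an expansin-like gene (LOC_Os06g50960) was 5.09-fold higher. Cellulose synthases had 1 of 31 higher, CSLF2 (at least 3.02-fold), and 1 lower, CSLF8 (2.52-fold), for a median of -0.14 (percentile 1.54). In the suberin, Casparian strip and silicon list, 2 of 7 were higher and 1 lower (median -0.18, percentile 9.32). All 3 are 3-ketoacyl-CoA synthases: LOC_Os01g34560 given above, LOC_Os06g15250 (at least 2.08-fold higher, under 2-fold with quantile normalization at a log2 ratio of 0.88) and LOC_Os03g12030 (4.69-fold lower). Of 2 root hair genes measured, an apyrase (LOC_Os12g02980) was at least 4.40-fold higher.

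Iron and metal homeostasis genes had 6 of 45 lower and 2 higher (median -0.10, percentile 0.63). Nicotianamine synthase 1, which makes a metal chelator, was 4.45-fold lower and LOC_Os02g43410, a yellow stripe-like transporter by its synonym, 5.84-fold lower, whereas a ZIP transporter (LOC_Os07g12890) was 2.73-fold higher. Potassium and sodium transporters had 6 of 39 higher and 1 lower, yet a list median of -0.20 (percentile 0.15), with 22 members under 0. Potassium transporter 17 was 28.6-fold higher and potassium transporter 5 was 3.59-fold lower. The channel AKT1 (LOC_Os01g45990) was 25.3-fold higher on a shared probe set. Aquaporins had 1 of 26 higher, NIP5.1 (3.96-fold), and 2 lower, PIP2.7 (at least 8.63-fold) and PIP1.3 (2.12-fold), with a median of -0.10 (percentile 3.21). Fermentation and carbohydrate genes had 2 of 37 higher and 3 lower (median -0.08, percentile 4.0). A gene described as alcohol dehydrogenase 1 (LOC_Os11g10480) was 2.07-fold higher on a shared probe set. The others of that name, LOC_Os02g42520 and LOC_Os03g08999, had log2 ratios of 0.15 and -0.49. A gene described as alcohol dehydrogenase 2 (LOC_Os10g07229) was 2.84-fold lower. The others of that name, LOC_Os11g10510 and LOC_Os11g10520, had log2 ratios of -0.003 and 0.32. Alpha-amylase isozyme 3D was at least 5.75-fold lower. Of 12 RNA silencing genes, 1 argonaute-like gene was 2.43-fold higher (LOC_Os07g28850) and another at least 5.71-fold lower (LOC_Os03g47830); the median of 0.02 (percentile 39.9) changed sign to -0.01 after median-centring. Seed storage genes, fixed as a marker of seed tissue, had 9 members measured, most of them at low signal. Of these, 2 were higher, among them the oleosin LOC_Os05g50110 (at least 3.43-fold), and 1 was higher with quantile normalization. The median of 0.09 (percentile 44.2) changed sign to -0.03 under that normalization.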

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

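The test of leaf marker genes was written before its result was seen; the other tests in this part were chosen only after the results they bear on were seen.

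The array carries 64 probe sets named as reporters, which belong to no gene list. They drew attention because they had signal in the transgenic sample alone: none was Present in wild type, where the highest read 46.02, and 8 were Present in transgenic roots, 7 of them at least 2-fold higher and so within the 2402 given for all probe sets (2395 without them). The signals of the brightest on the transgenic array were 21960.6, 19275.1, 12487.4, 10734.9 and 10441.9, against at most 15.6 for the same probe sets in wild type, a difference of at least 737-fold. Those reading 12487.4, 10734.9 and 10441.9 share 1 sequence identifier in their names, so they may read the same sequence. The sources used here do not say what the identifiers in the names stand for.

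Photosynthesis genes were lower in transgenic roots, with a median log2 ratio of -2.25. Scaling between the arrays is argued against, since the median was -2.27 after quantile normalization. More green shoot tissue in the wild-type sample stays open. Its test, on YABBY genes of leaves and other lateral shoot organs, gave a median of 1.20, the opposite of the direction it needs, but only 2 of the 9 YABBY genes on the array were measured, fewer than the 5 the test required. An effect of the genotype on root plastids may also underlie the difference and was not tested, since it falls together with the arrays.

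Transcripts Absent on 1 array and at least 16-fold brighter on the other numbered 145 probe sets higher in transgenic roots and 38 lower. Noise of dim probe sets stays open for the class as a whole. The ratio of the classes was 0.262. Probe sets Absent on both arrays lean the same way, with 2571 at least 2-fold higher and 1336 lower, a ratio of 0.52. These were taken at a lower threshold than the classes, so the ratio cannot decide. It also does not bear on the brightest members, such as the lipid-transfer protein LOC_Os10g36100, which read 19821 in transgenic roots. Chromosome segments that differ between the lines could account for a part of the lower genes. Of these, 5 of 33 (percentile 99.8 of 1000 random sets) had another of a different description within 10 measured genes. Among them were LOC_Os06g27860, LOC_Os06g28050 and LOC_Os06g28194, and the first and last of these counted through LOC_Os06g28050 alone. Other probe sets of LOC_Os06g28050 gave log2 ratios of -1.44 (Present on both arrays) and -1.24, well short of 16-fold. These hits therefore rest on 1 probe set of that gene. The count was 5 of 27 (percentile 100) when shared probe sets and those matching several loci were left out. For the higher genes segments stay open, since 19 of 111 (percentile 99.9) had such a neighbour but only 4 of 77 (percentile 68.2) without those probe sets, which can read the same transcript. Neighbours regulated together would give the same excess, and most genes had no such neighbour. An effect of the transgene stays open as an untested biological explanation.

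WRKY, jasmonate and pathogenesis-related genes were higher in transgenic roots. Members called Absent on 1 array do not carry the pattern alone. Among 190 members Present on both arrays, 48 were at least 2-fold higher and 9 lower, a ratio of 5.33. These lists were pooled because their medians were high, so the count restates the same values. Members called Present can also be dim, so noise cannot be excluded by this count. A response of the roots to the transgene may explain the difference, but so might any unequal stress or handling of the seedlings. With 1 array per genotype these cannot be told apart.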

How the results depend on the processing

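The settings without reporter probe sets, with the deposited 1-decimal values, without chloroplast-described probe sets, without the potassium channels and with list medians over genes Present on both arrays were chosen after seeing the data; the others were planned. Of 28 alternative counts, 21 stayed within 1.5 times the main count of 2402 higher and 2418 lower. The rest moved by construction: 1527 were higher with Present required on both arrays (1842 lower), 5120 higher and 3805 lower with no detection filter, 1165 and 1201 at 3-fold, and 4551 and 4405 at 1.5-fold. Quantile normalization gave 2113 and 2681, the deposited 1-decimal values 2403 and 2420, and leaving out reporters 2395 and 2418. No scaling moved the median log2 ratio of all probe sets Present on both arrays by over 0.1. Of the alternative list medians, 271 stayed inside the interval of the main median, and the 2 that left it did so under median-centring, which subtracts a constant: cytosolic ribosomal proteins at -0.0536 and heat shock proteins at -0.00414. Of the 121 named values counted past 2-fold, 5 were under 2-fold with quantile normalization, 4 with a doubled floor and 0 with no floor; none of these counted ratios changed sign, and the largest move under quantile normalization was 0.28 (log2), whose cause was not tested. No paired analysis was possible because each group has 1 array and no test was run. Signal over background limits the dim genes: 875 of the higher and 576 of the lower probe sets have only a bound on their fold.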

Other observations

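The lists and families in this part were chosen only after the results were seen, by grouping genes of similar description and taking those at either end, as were the single genes named. Their counts and medians carry no test, since a place far out among random lists restates that choice.

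Of 58 genes measured that are described as wall-associated kinases, a family with members that bind pectin, 24 were at least 2-fold higher and 3 lower. Their median log2 ratio was 0.48 (95% interval 0.11 to 1.09). The group also holds entries described as receptor-like cytoplasmic kinases, receptor-like proteins, short genes and pseudogenes, some of them among the higher ones. OsWAK105 and OsWAK103 read 13.3 and 16.9 in wild type and 7701 and 5127 in transgenic roots, both on probe sets marked as shared with related sequences, so a single transcript could account for both values. Lectin receptor kinases had 8 of 15 higher and 1 lower (median 1.01). Of 85 genes described only as receptor-like kinases, 14 were higher and 5 lower (median 0.13). Among ZIM-motif genes, 16 of 17 had a ratio above 0 and 8 were at least 2-fold higher (median 0.78, 95% interval 0.39 to 2.70). The family described as ATFP, small proteins related to heavy metal binding and farnesylated proteins, had 7 of 10 higher and none lower (median 1.67). Nonspecific lipid-transfer proteins had 8 of 19 higher and 3 lower (median 0.33, 95% interval -0.61 to 2.15), and methyltransferases of the SABATH type, which methylate small acids, 8 of 19 higher and 4 lower (median 0.33, 95% interval -0.97 to 3.52), and both intervals include 0. All 8 higher methyltransferases were Absent in wild type, and among the 9 members Present on both arrays none was higher and 4 were lower. Of the 12 lipid-transfer proteins Present on both arrays, 2 were higher and 3 lower.

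Chloroplast ribosomal proteins had 20 of 25 at least 2-fold lower and none higher (median -1.75), Calvin cycle genes 10 of 14 lower (median -1.82, 95% interval -3.37 to -0.67) and chlorophyll synthesis genes 8 of 16 lower (median -1.01). Sedoheptulose-1,7-bisphosphatase was 11.8-fold lower and phosphoribulokinase 9.88-fold. Photorespiration genes had 4 of 15 lower and a median of 0.01 (95% interval -1.02 to 0.03), but the lower ones included a glycine cleavage H protein (LOC_Os10g37180, 26.7-fold), hydroxypyruvate reductase (14.1-fold) and serine-glyoxylate aminotransferase (3.21-fold). Other families at the low end do not form a class: glycerol-3-phosphate acyltransferases, which take part in cutin and suberin synthesis, had 4 of 9 lower and none higher (median -0.94), cortical cell delineating proteins 1 of 12 lower with a median of -0.83, and glycine-rich cell wall proteins 7 of 20 lower and 2 higher (median -0.69). In all, 27 of 321 families of at least 8 genes lay above the central 95% of matched lists and 30 under it.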
